A study of Mus musculus with 18 samples.

How the data were processed

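Mouse cardiomyocytes of Mlc2vcre:R26REYFP hearts were sorted into mononucleated and binucleated cells at E18.5, P7 and in the adult, 3 libraries per group and 18 in all. Per the labels' protocols, cells were sorted straight into Trizol-LS; how nuclear number was told apart, and whether the sort used the yellow protein or a DNA dye, is not given in the sources used here. They further state that RNA was extracted with phenol-chloroform and purified on RNeasy micro columns, and libraries were made with an Illumina TruSeq stranded mRNA kit and a Clontech SMARTer amplification kit. Per the submitters' processing notes, STAR and limma were used with genome build mm9; their versions, the read counter, the annotation release and any filter on genes are not given in the sources used here. An amplified library repeats molecules and the values carry no molecular identifiers, so counting intervals and floors cover counting error only. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

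The authors deposited log2 values, 1 table per library with 12048 Ensembl gene identifiers. In every library the values had the form log2 of a whole read count plus 0.5 times 1 factor per library. Counts recovered from this form lay within 9.6e-09 of whole numbers (100% within a tolerance of 0.001), and the library factors departed by at most 0.0054% from TMM effective library sizes over the listed genes. The deposited log2 scale is therefore log2 CPM plus a constant that no source used here states, and levels are given only as differences, folds or recovered counts. Fold changes on this scale understate the change of genes with few counts, because of the offset of 0.5. Recovered totals ran from 14833334 to 22690952 counts per library. Replicates of 1 group differed by more than sampling noise (chi-square per degree of freedom from 13.5 to 254), so none looked like a copy of another, and each was counted on its own; whether they are separate animals is not shown by this.

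Gene symbols were looked up by Ensembl identifier in the GENCODE M21 name table: 11927 identifiers matched, 0 more matched through RefSeq, and 121 stayed without a symbol. The values come from mm9 and the reference used here is of another build, so no coordinates are given. Transcript length and GC content for the checks on library bias came from the same GENCODE release. Genes that share reads with close copies, such as the globin, histone and ribosomal protein families, are uncertain, because the treatment of shared reads is not given in the sources used here.

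All choices of tests, gene lists and alternatives were made before the data were examined, except where said otherwise. The design foresaw either log2 values or counts; since the tables were already log2, limma 3.58.1 (R 4.3.3) was run on the deposited values with no pseudocount, so the planned pseudocount alternative did not apply. 1 linear model with the means of the 6 groups was fitted to all 18 libraries, which left 12 residual degrees of freedom, with empirical Bayes moderation and an intensity trend. The 9 contrasts were binucleated against mononucleated at each age, P7 against E18.5 and adult against P7 within each class, and the 2 interactions of age and class. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within a contrast over all 12048 genes, and the threshold was 0.05. The planned filter, a log2 value of at least 0 in at least 3 libraries, removed 0 genes, and an added filter of at least 10 recovered counts in at least 3 libraries kept all 12048, so neither says anything about stability.

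Gene lists, fixed beforehand, numbered 29 with 696 members, 620 of them measured; the list of nuclear-retained long RNAs had 0 measured members and 28 lists were tested. They covered DNA replication and G1/S, G2/M and mitosis, cytokinesis, E2f, Rb and cyclin regulators, CDK inhibitors and p53 response, centrosome, nuclear envelope, replication-dependent histones, fetal cardiac isoforms, fetal growth and imprinted genes, excitation-contraction and sarcomere, fatty acid oxidation, oxidative phosphorylation, glycolysis, ribosomal proteins, Yap targets, immediate early genes, interferon response, ventricular, atrial and conduction markers, fibroblast, endothelial, pericyte, leukocyte, erythroid and epicardial markers, and sex-linked genes. Sets were tested with limma's camera at its preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry, each adjusted over the 28 lists of a contrast. A list's median is the median log2 fold change of its measured members.

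Genes are named by a rule: in class contrasts up to 6 per direction with the largest absolute log2 fold change among genes past the threshold whose 3 values per class did not overlap (chance gives 10% for 3 against 3) and whose mean was in the upper 75% of genes, up to 3 per list with the smallest adjusted p, and always Myl2, Tnnt2, Myh6, Myh7, Tnni1, Tnni3, Nppa, Mki67, Ccnb1, Aurkb, Kif23, Racgap1, Ect2, Anln, E2f1 and Rb1. Age contrasts used up to 4 per direction and 2 per list, and interactions up to 4 per direction. Genes known only by a clone or model number are counted and not named, and only part of the genes so chosen are written out; 1 gene is not reported here. Where a gene had 0 counts over a group, the fold is a lower bound against a floor of 3 counts over the group; at 1 to 3 counts the ratio is given with its exact binomial 95% counting interval.

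Libraries of 1 age share replicate numbers. Deviations from the group means correlated between same-numbered libraries at 0.18 to 0.24 at P7 and 0.26 to 0.33 in the adult, over 0.1 in every pair, and these numbers were treated as pairs; the pairing comes from the values, not from the labels. At E18.5 the correlations were 0.05 to 0.16 and between ages −0.13 to 0.14, and those numbers were not treated as pairs. Differently numbered E18.5 libraries of opposite class correlated at −0.09 to 0, so a weak pairing at E18.5 is not excluded. A block at P7 and in the adult alone was added after the data were seen. Blocked values are given beside a P7 or adult result only where they change a call or move a count by over 1.5 times.

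Alternatives chosen beforehand were the replicate block, quantile normalization, a log2 fold of at least 1, robust moderation without a trend, a fit of only the libraries compared, no filter, an estimated correlation for sets, and leaving out each library. Added after the data were seen were limma's voom weights on the recovered counts, array weights, the count filter, scaling to total counts, and leaving out E18.5 binucleated replicate 1 where it is not in the groups compared. The method was tested on simulated counts with 200 of 12048 genes changed: at log2 changes of 1 and 2 it recovered 39% and 83% for the E18.5 class contrast, 43% and 77% for P7, and 55% and 85% for the adult, and false genes made up 5.43%, 7.69% and 6.04% of its calls. The simulated genes were independent, with the same spread in every library, no outlying library and no pairs. Only genes with a mean recovered count of at least 10 were changed. These rates therefore do not measure the share of false calls in the real data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.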

Results

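Transcripts were measured in mouse cardiomyocytes that had been sorted by their number of nuclei. The hearts came from Mlc2vcre:R26REYFP mice, in which Cre recombinase driven by Mlc2v (Myl2, the ventricular regulatory myosin light chain gene) switches on a yellow fluorescent protein. Sorting gave mononucleated and binucleated cells at E18.5 shortly before birth, at P7 after it and in the adult. There were 3 libraries in each of the 6 groups and 18 libraries in all. The series set both classes side by side to ask which transcripts go with their different capacity to proliferate. The deposited table of each library listed 12048 genes. The whole counts recovered from it summed to 19951367 to 22690952 per library in the E18.5 mononucleated group and 14833334 to 22053711 in the E18.5 binucleated group. The totals were 16476191 to 20909939 in P7 mononucleated and 16214426 to 19688424 in P7 binucleated libraries. In the adult they were 16927731 to 20946659 in mononucleated and 17644666 to 20278587 in binucleated libraries.

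Age separated the libraries more than nuclear class did. The first principal component held 63.5% of the variance and the second 12.1%, and the ages lay apart in their plane. Replicates correlated at 0.954 to 0.983 within 5 groups and at 0.884 to 0.964 within the E18.5 binucleated group. Binucleated replicate 1 at E18.5, the library of lowest total count, stood alone on the third component, which held 5.9% of the variance. Its values differed from the mean of the rest of its group with an SD over genes of 1.22 log2 units, against 0.69 to 0.84 for the 5 other E18.5 libraries.

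**Figure D1:**
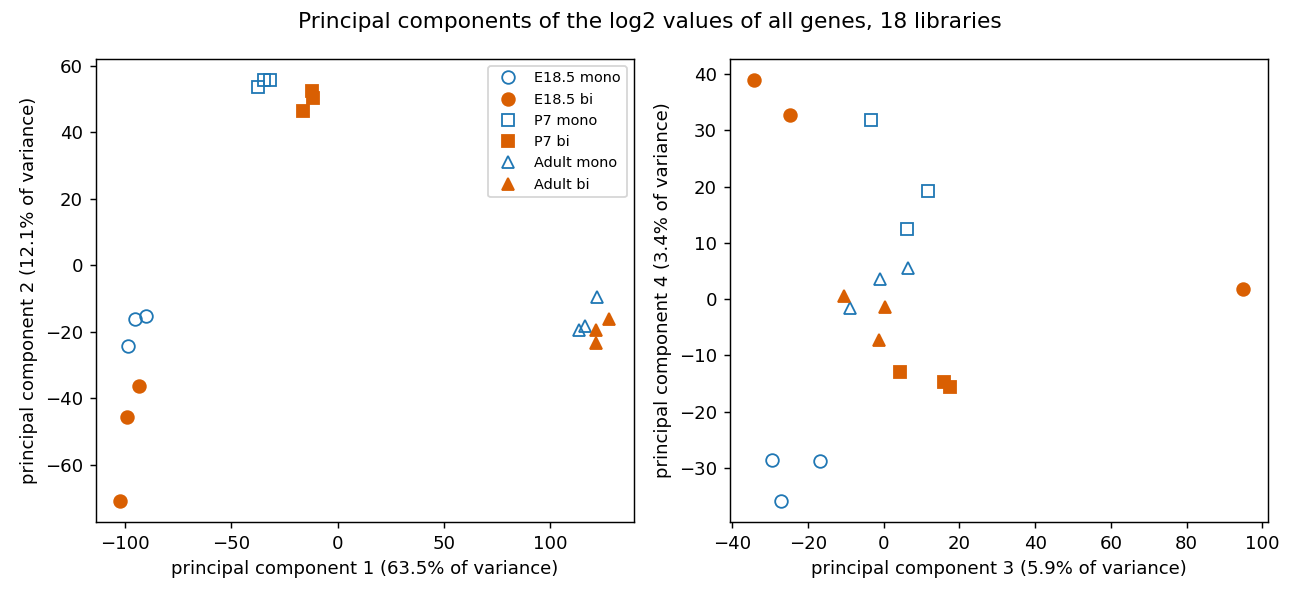
Principal components of the log2 values of 12048 genes, with 1 point per library (18 libraries, 3 per group), colored by nuclear class and shaped by age. Axes give component scores in log2 units and the percent of variance. On the left the ages separate along components 1 (63.5%) and 2 (12.1%); on the right, E18.5 binucleated replicate 1 lies apart from all other libraries on component 3 (5.9%).

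At E18.5, binucleated libraries held more transcripts of fibroblast, endothelial, leukocyte and mitotic genes than mononucleated libraries. Of 15 measured fibroblast markers 7 were higher, among them Dcn, the gene of the matrix proteoglycan decorin (ENSMUSG00000019929; 17-fold, log2 fold change 4.09 ± 0.52 SE, n = 3 per class, limma adjusted p = 0.000853). Others were Col5a1, a chain of type V collagen (7.66-fold, limma adjusted p = 0.00272), and Postn, the gene of periostin (6.86-fold, limma adjusted p = 0.00289). Of 17 endothelial markers 8 were higher, including the endothelial sialomucin gene Emcn (10.3-fold, log2 fold change 3.37 ± 0.47 SE) and Cd93 (7.67-fold), a lectin-like receptor of endothelial cells. Of 7 leukocyte markers 5 were higher. Laptm5, a lysosomal protein of blood cells, had 105 recovered counts over the binucleated libraries and 0 over the mononucleated ones (at least 37.6-fold higher). The macrophage complement genes C1qc and C1qb were at least 37.2-fold and 30-fold higher. Pdgfrb, a receptor of pericytes, was at least 137-fold higher and was the 1 of 9 pericyte and smooth muscle markers that passed the test. All 59 measured G2/M and mitosis genes had a fold change above 1, with a median log2 fold change of 0.82, and 3 of them passed the test over all genes.

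Those 3 genes of the G2/M list were Cenpf, a kinetochore protein gene (ENSMUSG00000026605, 2.67-fold, log2 fold change 1.42 ± 0.15 SE, limma adjusted p = 0.000359), the centromeric histone gene Cenpa (log2 fold change 1.22, limma adjusted p = 0.0296) and the cohesin protector gene Sgo2a (1.19, limma adjusted p = 0.0284). Without E18.5 mononucleated replicate 1, the limma adjusted p was 0.144 for Cenpa and 0.127 for Sgo2a. Adjusted over the list alone, 16 G2/M genes were higher, as were 12 fibroblast, 15 endothelial and 6 leukocyte markers. The DNA replication and G1/S genes did not go with the mitotic ones: 0 of 51 passed the limma test and the list median was −0.11 (camera adjusted p = 0.53). Ccnb1, the mitotic cyclin, had a log2 fold change of 1.47 ± 0.41 SE (limma adjusted p = 0.145). The cytokinesis genes Kif23, Racgap1, Ect2 and Anln had values of 1.04 ± 0.7, 0.65 ± 0.5, 0.71 ± 0.58 and 0.6 ± 0.37, none past the threshold. In all, 97 genes passed, 89 higher and 8 lower in binucleated cells. At an unadjusted p under 0.05 there were 1679. Of the 89, 21 were among the 61 measured markers of other cell types and 3 among the 195 cell cycle genes. The lower genes included Itga7, a laminin-binding integrin subunit of muscle, whose log2 fold change of −1.04 lost its call without E18.5 mononucleated replicate 1 (limma adjusted p from 0.0485 to 0.15).

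Set tests at E18.5 called 10 of 28 lists with camera's preset correlation of 0.01. Of these, 4 held with an estimated correlation, whose adjusted p is called the estimated-correlation p here: G2/M (adjusted p = 0.014 with an estimated correlation), fibroblast (median 3.14, estimated-correlation p = 0.011), endothelial (median 2.59, estimated-correlation p = 0.00099) and leukocyte (median 3.9, also with genes at 0 set to their bound, estimated-correlation p = 0.00099). The calls of cytokinesis machinery (median 0.33), replication-dependent histones (0.88), fatty acid oxidation (−0.1), oxidative phosphorylation (0.22), cytosolic ribosomal proteins (0.4) and epicardial markers (1.39) were lost, with adjusted p = 0.33, 0.49, 0.49, 0.68, 0.56 and 0.35 with an estimated correlation. With the preset correlation, cytokinesis and epicardial markers also lost their calls without binucleated replicate 3 (camera adjusted p = 0.198 and 0.193), histones without binucleated replicate 1 (0.322) and fatty acid oxidation without binucleated replicate 2 (0.259). Fry, which tests whether a list's genes move on balance one way, gave adjusted p = 0.0012 for G2/M genes. The oxidative phosphorylation and ribosomal medians turned to −0.137 and −0.104 without binucleated replicate 1. That library held less of the fibroblast, endothelial and leukocyte markers than the other E18.5 binucleated libraries. Without it the fibroblast, endothelial, leukocyte and G2/M medians were 3.84, 3.08, 4.91 and 0.9. The number of genes called varied more with the libraries used. It was 282 (118 higher, 164 lower) without binucleated replicate 3, 84 higher and 29 lower after quantile normalization, and 0 when limma was fitted to the 6 E18.5 libraries alone.

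At P7, transcripts of genome replication were lower in binucleated than in mononucleated cells. Of the 51 DNA replication and G1/S genes 40 were lower, and all 51 adjusted over the list alone, with a median log2 fold change of −2.08. Ccne2, the gene of cyclin E2, stood 7.5-fold lower (ENSMUSG00000028212; log2 fold change −2.91 ± 0.24 SE, n = 3 per class, limma adjusted p = 1.68e-05), and the replicative helicase subunit gene Mcm6 5.82-fold lower (ENSMUSG00000026355; −2.54 ± 0.29 SE, limma adjusted p = 0.000185). Rrm2, a subunit of ribonucleotide reductase, was 3.62-fold lower. The single-strand DNA binding subunit gene Rpa2 was 3.27-fold lower and the origin licensing factor gene Cdt1 7.8-fold lower. The transcription factor gene E2f1, an activator of S-phase genes, was 6.48-fold lower (−2.7 ± 0.33 SE, limma adjusted p = 0.000282). Ccne1, the gene of cyclin E1, was 5.11-fold lower. They belonged to 9 of 27 E2f, Rb and cyclin regulators that were lower, whereas Rb1 had a log2 fold change of 0.12 ± 0.37 SE (limma adjusted p = 0.995).

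Mitotic genes had a smaller median difference at P7. Of 59 G2/M genes 8 were lower (median −1.06; 21 adjusted over the list alone). They included the topoisomerase gene Top2a (−1.45 ± 0.23 SE, limma adjusted p = 0.00198), the condensin gene Smc2 (−1.48) and the spindle checkpoint gene Mad2l1 (−1.11). Of 22 centrosome genes 4 were lower, including Tubg1, the gene of gamma-tubulin (−0.82 ± 0.11 SE, limma adjusted p = 0.000624). Of 31 cytokinesis genes 1 was lower, the chromosomal passenger gene Incenp (−1.31, limma adjusted p = 0.00702, and 0.051 without P7 mononucleated replicate 3). Aurkb, the kinase of that complex, had −1.73 ± 0.52 SE (limma adjusted p = 0.122, 0.0134 with the replicate number as a block and 0.00748 with it as a block at P7 and in the adult alone, where numbers pair the libraries). Kif23, Racgap1, Ect2 and Anln had −0.58 ± 0.7, −0.5 ± 0.5, −0.7 ± 0.58 and −0.6 ± 0.37, with limma adjusted p from 0.717 to 0.962. Mki67 (−0.98 ± 0.42 SE) and Ccnb1 (−0.18 ± 0.41 SE) did not pass either.

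Conduction system markers also separated the classes at P7, and fatty acid oxidation genes did so as a set. Of 9 conduction system markers 4 were lower in binucleated cells (median −2.13; 7 adjusted over the list alone). Among them were Gja5, the connexin of atrial and Purkinje cells (7.72-fold, −2.95 ± 0.45 SE, limma adjusted p = 0.00148), the transcription factor gene Etv1 (4.37-fold, −2.13 ± 0.23 SE), and the sodium channel gene Scn10a (6.09-fold, −2.61 ± 0.44 SE). Bmp10, a growth factor of atrial muscle, had 88 counts in mononucleated and 2 in binucleated libraries, a ratio of 38.3 (95% exact counting interval 10.3 to 321; limma adjusted p = 0.00174). The imprinted gene Mest was 5.51-fold lower (−2.46 ± 0.26 SE, limma adjusted p = 0.000132). On the other side, all 31 fatty acid oxidation genes had a fold change above 1 (median 0.31), although 0 passed the limma test over all genes and 9 did when adjusted over the list alone. The mature excitation-contraction and sarcomere list (median 0.23; 0 of 32 past the threshold) and the ventricular identity list (median 0.27; 0 of 12) were also higher as sets. Of the 8 genes that passed in the upward direction, Cavin4, a caveolar coat protein of muscle, was 1.65-fold higher (0.73 ± 0.11 SE, limma adjusted p = 0.00116) and the lipoprotein receptor gene Vldlr 1.55-fold (0.63 ± 0.09 SE, limma adjusted p = 0.000947).

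In all, 256 genes passed at P7, 8 higher and 248 lower in binucleated cells, with 1210 at an unadjusted p under 0.05. Of the 248, 62 were cell cycle genes and 4 other-cell markers. Camera called 13 lists, and 8 held with an estimated correlation: replication (adjusted p = 0.00027 with an estimated correlation), G2/M (0.0039), E2f and cyclin regulators (median −0.41, estimated-correlation p = 0.00042), centrosome (median −0.27, estimated-correlation p = 0.0024), conduction (0.0034), excitation-contraction (0.0034), fatty acid oxidation (0.0024) and ventricular identity (0.019). Cytokinesis (median −0.46), histones (−1.18), oxidative phosphorylation (0.23), atrial markers (−0.45) and fibroblast markers (−0.56, 2 of 15 lower) were called by camera alone, with adjusted p = 0.22, 0.22, 0.5, 0.12 and 0.24 with an estimated correlation. The fibroblast and cytokinesis calls were also lost without P7 mononucleated replicate 1 (camera adjusted p = 0.0951) and binucleated replicate 3 (0.153). The count fell to 163, 158 and 129 without P7 mononucleated replicates 1, 2 and 3 and to 166, 135 and 165 without P7 binucleated replicates 1, 2 and 3. It was 574 (99 higher, 475 lower) without E18.5 binucleated replicate 1, which enters the shared estimate of spread. A fit of the P7 libraries alone gave 608 (53 higher, 555 lower), and array weights gave 1401 (439 higher, 962 lower). Most genes called were lower in each fit, but the share of higher ones depended on the estimate of spread.

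**Figure D2:**
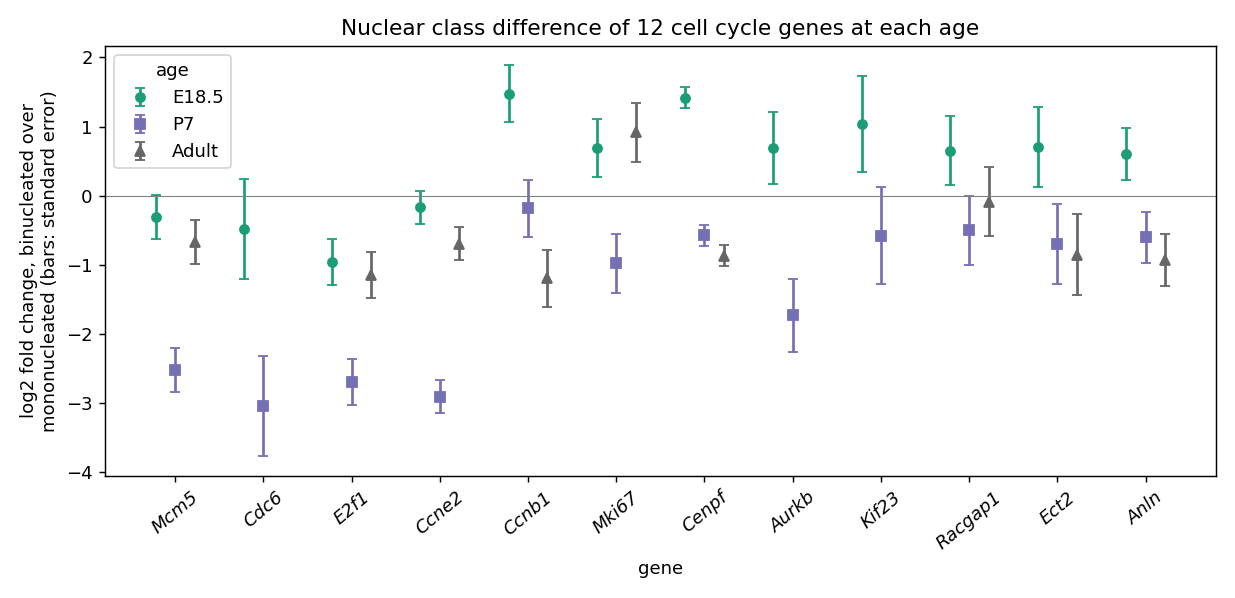
Log2 fold change of binucleated over mononucleated cells (y axis; bars, standard error of the limma fit, n = 3 libraries per class) for 12 cell cycle genes (x axis) at E18.5, P7 and in the adult. Adult Cdc6, Aurkb and Kif23, with 3 or fewer counts in a class, are not drawn. At P7 the replication and E2f genes lie lowest (Ccne2 −2.91, E2f1 −2.7), while at E18.5 the mitotic and cytokinesis genes lie above 0 (Cenpf 1.42, Ccnb1 1.47).

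In adult hearts few genes passed the test between the classes. Top2a was 3.81-fold lower in binucleated cells (−1.93 ± 0.23 SE, n = 3 per class, limma adjusted p = 0.00193). Ndn, the imprinted gene of the growth regulator necdin, was 3.99-fold lower (−2 ± 0.23 SE, limma adjusted p = 0.00193). Cenpf was 1.82-fold lower (−0.87 ± 0.15 SE, limma adjusted p = 0.0333; 0.0505 with the block, 0.0578 with the block at P7 and in the adult alone, and 0.165 without adult binucleated replicate 1). Cenpf had 4314 recovered counts in adult mononucleated and 2354 in adult binucleated libraries, against 1984 and 1147 at P7. Mki67 had 37 and 82 in the adult, so Cenpf did not mark mitosis alone there. The mitotic gene Pimreg had 11 recovered counts in binucleated and 0 in mononucleated libraries, at least 3.64-fold higher, a call lost without adult mononucleated replicate 1 (limma adjusted p from 0.0284 to 0.0692). Nppa, the gene of atrial natriuretic peptide (−2.39 ± 0.72 SE; limma adjusted p = 0.61), was lower with the block (0.00355) and with the block at P7 and in the adult alone (0.0335). The conduction genes Etv1 and Cntn2 (0.284 and 0.327) passed with the block (0.0473 and 0.04) and not with the narrower one (0.111 and 0.623).

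In all, 11 genes passed in the adult, 1 higher and 10 lower, with 301 at an unadjusted p under 0.05. Those 301 are fewer than a share of 0.05 of the 12048 genes, the average with no class difference. The test may thus have been conservative in the adult, and a low count does not show that the classes are alike. A total of 25 passed with the block, 9 of them in both fits, and 14 with the block at P7 and in the adult alone, 8 of them in both. Camera called 7 lists, and 2 held with an estimated correlation. These were conduction system markers (median −0.57; adjusted p = 0.022 with an estimated correlation; 0 of 9 past the limma test and 4 adjusted over the list alone) and fetal growth and imprinted genes (median −0.27, estimated-correlation p = 0.022). Fry called neither (adjusted p = 0.068 for both). The lists of replication (−0.15), G2/M (−0.2; 13 lower and 1 higher adjusted over the list alone), fatty acid oxidation (0.07), atrial (−0.53) and erythroid genes (−1.1) were called by camera only, with adjusted p = 0.52, 0.2, 0.26, 0.2 and 0.39 with an estimated correlation. With the block, camera also called fetal cardiac isoforms and stress genes (adjusted p from 0.081 to 0.0024), endothelial markers (0.12 to 0.047) and sex-linked genes (0.18 to 0.013); with the narrower block these were 0.025, 0.088 and 0.042. With an estimated correlation, and no block, they had adjusted p = 0.39, 0.52 and 0.67. The count was 2 without adult mononucleated replicate 2, 23 without E18.5 binucleated replicate 1, 5 after quantile normalization (1 higher, 4 lower), and 0 both in a fit of the adult libraries alone and with limma's voom weights. Losing 1 library also ended the camera calls of replication (0.0851 without mononucleated replicate 3), fatty acid oxidation (0.0833 without mononucleated replicate 1), atrial markers (0.344 without mononucleated replicate 2, where the median was 0.065) and erythroid markers (0.677 without binucleated replicate 1).

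The contractile genes followed at every age gave no call between the classes. Myl2, Tnnt2, Myh6, Myh7, Tnni1 and Tnni3, which encode light chain, troponin and myosin heavy chain isoforms of the sarcomere, had log2 fold changes from −0.78 (Myh6 and Myh7 at E18.5) to 0.36 (Myh6 at P7), with limma adjusted p of 0.344 or more. Lists that camera, without the block, called at none of the 3 ages were CDK inhibitors and p53 response (medians 0.17, 0.06 and −0.07 at E18.5, P7 and in the adult), nuclear envelope and lamina (−0.01, −0.05, −0.02), glycolysis and glucose uptake (0.02, 0.14, 0.02), Yap targets (−0.17, −0.05, −0.01), immediate early and dissociation stress genes (0.09, −0.06, 0.02), interferon response (0.31, −0.08, −0.05), pericyte markers (0.48, −0.39, −0.06), fetal cardiac isoforms (0, 0.04, −0.03) and sex-linked genes (−0.23, 0.31, 0.31).

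**Figure D3:**
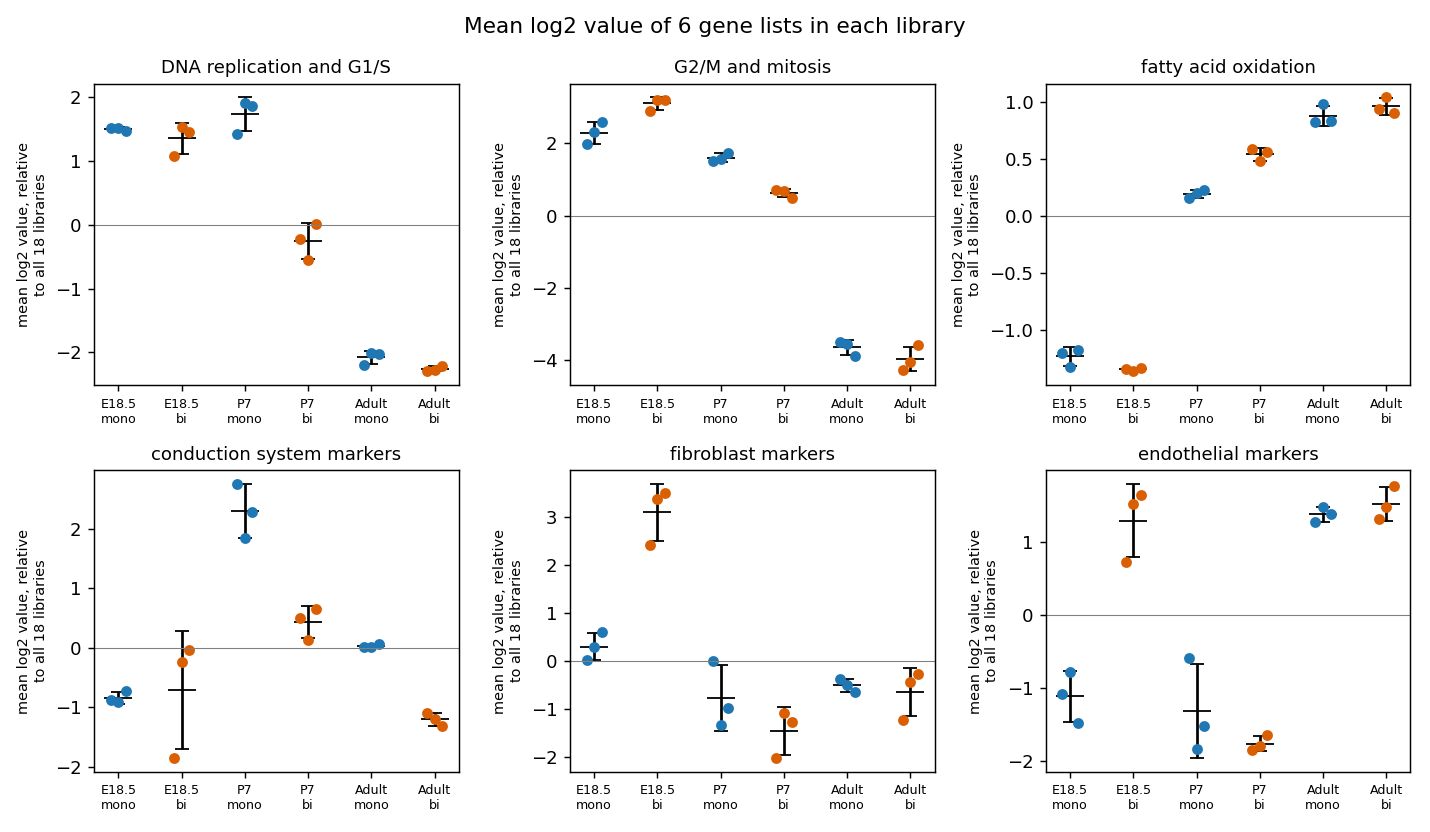
Mean log2 value of 6 gene lists in each library relative to the mean of all 18 libraries (y axis, log2 units) by age and nuclear class (x axis); points are libraries, bars the mean ± SD (n = 3). Replication genes averaged 1.73 ± 0.26 in P7 mononucleated and −0.25 ± 0.28 in P7 binucleated libraries; fibroblast markers averaged 3.1 ± 0.59 in E18.5 binucleated and 0.3 ± 0.29 in E18.5 mononucleated libraries.

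The test of the difference between ages, the interaction of age and class, showed where the class difference itself moved. From E18.5 to P7 it changed in 281 genes, 253 of them toward lower values in binucleated cells, with 1775 at an unadjusted p under 0.05. Neil3, a DNA glycosylase gene of cycling cells, went from a class log2 fold change of 1.02 at E18.5 to −2.18 at P7 (limma adjusted p = 0.00542), and Plin5, a lipid droplet protein of oxidative muscle, from −0.78 to 0.49 (limma adjusted p = 0.0198). Of the 253, 45 were cell cycle genes and 19 other-cell markers. Without 1 library the count was 185, 176 and 160 (P7 mononucleated replicates 1, 2 and 3), 163 and 170 (P7 binucleated replicates 2 and 3) or 568 (E18.5 binucleated replicate 1, with 127 higher and 441 lower). Plin5 lost its call in 5 of 12 such fits, reaching 0.0563 without P7 binucleated replicate 3, and with the block at P7 and in the adult alone (0.0698). From P7 to the adult the class difference changed in 25 genes, all 25 toward higher values in binucleated relative to mononucleated cells. At an unadjusted p under 0.05 there were 568, fewer than a share of 0.05 of the 12048 genes. Of the 25, 11 were cell cycle genes. Ccne2 went from −2.91 at P7 to −0.69 in the adult (limma adjusted p = 0.0163; 0.0547 with the block, 0.0439 with the block at P7 and in the adult alone and 0.08 without P7 mononucleated replicate 3). That count was 12 with the block and 8 with the narrower one, 8 of them in both fits each time, and ran from 0 to 102 when 1 library was left out.

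Between E18.5 and P7, transcripts of fatty acid metabolism rose and those of fetal growth genes fell in libraries of both classes. In every comparison of ages, age cannot be told apart from differences between ages in cell isolation, sorting or library preparation. Such differences were not tested. In mononucleated cells the mitochondrial carrier gene Ucp2 rose by 5.78 ± 0.28 (SE, log2 units, limma) and Angptl4, a lipase inhibitor induced by fatty acids, by 5.6 ± 0.48. Ucp3, the uncoupling protein gene of muscle, went from 0 to 5141 recovered counts (at least 1990-fold higher). Of 31 fatty acid oxidation genes 23 rose and 0 fell (median 0.83; limma, adjusted p = 0.0022 with an estimated correlation in camera). Of 16 fetal growth and imprinted genes 12 fell (median −2.3, estimated-correlation p = 0.0022), Mest by 3.27 and Gpc3, a membrane proteoglycan gene, by 4.71 ± 0.59. Myh7, the slow myosin heavy chain gene, fell by 3.74 ± 0.41 (limma adjusted p = 7.44e-06). The glucose and lactate transporter genes Slc2a1 and Slc16a3 fell by 3.25 and 4.44, while glycolysis as a list (4 rose, 11 fell) was not called with an estimated correlation (adjusted p = 0.085). Of 9 conduction markers 8 rose (median 2.16; adjusted p = 0.018 with an estimated correlation), Etv1 by 2.11, and 11 of 32 excitation-contraction genes rose and 1 fell (median 0.39, estimated-correlation p = 0.018).

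Cell cycle genes parted the classes over this interval. In mononucleated cells 2 replication genes rose and 0 fell (median 0.27, camera adjusted p = 0.16). In the same cells 10 of 59 G2/M genes fell and 0 rose, and 8 of 31 cytokinesis genes fell and 2 rose. Ect2, the exchange factor that starts the cleavage furrow, fell by 2.66 (limma adjusted p = 0.00387), but neither list held with an estimated correlation (adjusted p = 0.2 and 0.085). In binucleated cells 45 of 51 replication genes (median −1.6, estimated-correlation p = 0.023), 57 of 59 G2/M genes (median −2.6, estimated-correlation p = 0.0028) and 20 of 31 cytokinesis genes (median −1.61, estimated-correlation p = 0.014) fell, and 0, 0 and 3 rose. Cenpf fell by 2.84 ± 0.15, Ccnb1 fell by 3.15, Mki67 fell by 2.22 and Rrm2 fell by 1.91. Their fatty acid oxidation genes rose in 26 of 31 cases (median 1.11, estimated-correlation p = 0.0023), and Plin5 rose by 4.65 ± 0.19. Likewise 21 of 32 excitation-contraction genes rose (median 0.87, estimated-correlation p = 0.0023), among them Myh6, the fast myosin heavy chain gene, by 1.81 (limma adjusted p = 0.000741). Markers of other cells fell in binucleated libraries: 14 of 15 fibroblast (median −5.44, estimated-correlation p = 0.021), 15 of 17 endothelial (−2.95, estimated-correlation p = 0.014) and 6 of 7 leukocyte markers (−3.12, estimated-correlation p = 0.024), and Col1a1, a chain of type I collagen, had a log2 fold change of −6.24 ± 0.79 SE (limma adjusted p = 1.95e-05). Mononucleated libraries showed 5 of 15 fibroblast markers lower and 1 higher (median −1.15; adjusted p = 0.48 with an estimated correlation).

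In all, 2231 genes changed from E18.5 to P7 in mononucleated cells (1286 rose, 945 fell) and 4332 in binucleated cells (2198 rose, 2134 fell). The camera calls numbered 11 and 16, of which 4 and 11 held with an estimated correlation. The oxidative phosphorylation call (medians 0.28 and 0.31) did not (0.8 and 0.62), and its binucleated median was 0 after quantile normalization. Ribosomal protein genes had medians of −0.4 and −0.71 (1 and 33 of 73 fell, camera adjusted p = 0.8 and 0.49 with an estimated correlation). The larger binucleated fall rested on E18.5 binucleated replicate 1, whose ribosomal genes lay 1.54 above its fellow libraries. Without it, the ribosomal median in the interaction went from −0.31 to 0.186. Atrial marker medians were −1.65 and −4.19 (in binucleated cells 6 of 8 fell, estimated-correlation p = 0.073). In binucleated cells Myl7, the atrial light chain gene, fell by 6.92. Scaling to total counts gave 1087 higher and 1223 lower genes in mononucleated cells, and in binucleated cells it brought the median of all genes to −0.16 (from 0.03) and gave 1385 higher and 3099 lower. The mononucleated count was 3901 without E18.5 binucleated replicate 1, 3875 in a fit of those 6 libraries alone and 1197 with a fold of at least 1 log2 unit; the binucleated count was 2069 and 2265 in the last 2 settings.

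From P7 to the adult, cell cycle transcripts and the fetal troponin isoform fell in both classes. Tnni1, the fetal troponin I gene, fell by 10.22 ± 0.35 in mononucleated (79699 to 60 recovered counts, limma adjusted p = 1.58e-11) and by 10.56 ± 0.35 in binucleated cells. In mononucleated cells 51 of 51 replication genes (median −3.16; adjusted p = 0.0093 with an estimated correlation), 55 of 59 G2/M genes (−5.85, estimated-correlation p = 0.004) and 22 of 31 cytokinesis genes (−2.6, estimated-correlation p = 0.0093) fell, and 0, 2 and 1 rose. In binucleated cells 38 of 51 (−1.66, estimated-correlation p = 0.067), 52 of 59 (−4.89, estimated-correlation p = 0.0057) and 20 of 31 (−2.46, estimated-correlation p = 0.011) did, with 0, 2 and 1 higher, the replication list being called by camera's preset alone. Top2a had log2 fold changes of −5.85 and −6.32 and Rrm2 of −5.22 and −3.76 in mononucleated and binucleated cells. Aurkb was down to 1 and 2 counts, ratios of 773 (95% exact counting interval 138 to 30500) and 120 (32.9 to 996). Fetal growth genes fell too (11 of 16 in each class, with 1 higher in mononucleated cells; medians −2.26 and −2.68, estimated-correlation p = 0.018 and 0.013), with log2 fold changes of −7.16 and −7.14 for Igf2, a fetal growth factor gene.

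Some metabolic and excitation genes rose over the same interval, although with an estimated correlation the lists of fatty acid oxidation and excitation-contraction were called in mononucleated cells and not in binucleated ones. Bdh1, a ketone-oxidizing dehydrogenase gene, rose by 8.08 ± 0.29 in mononucleated and 7.99 in binucleated cells (limma adjusted p = 1.58e-11 in the former), the carboxylesterase gene Ces1d by 7.12 and 7.21, and Scn4b, a sodium channel beta subunit gene, by 6.12 and 6. Fatty acid oxidation genes rose in 23 and 17 of 31 cases and fell in 1 and 1 (medians 0.62 and 0.38; adjusted p = 0.016 and 0.07 with an estimated correlation), as did excitation-contraction genes in 20 and 9 of 32, with 1 and 2 lower (0.61 and 0.4, estimated-correlation p = 0.01 and 0.067). Slc2a4, the insulin-responsive glucose transporter gene, rose by 1.64 and 1.73. Oxidative phosphorylation medians of 0.34 and 0.12 (0.69 and 0.82 with an estimated correlation) turned to −0.156 and −0.202 after quantile normalization, and the mononucleated glycolysis median of 0.36 (0.17) to −0.092. Of 61 markers of other cells 28 rose in each class, while 9 fell in mononucleated and 10 in binucleated cells. By type, 15 of 17 endothelial markers rose in each class (medians 2.84 and 3.18, estimated-correlation p = 0.022 and 0.015), such as Fabp4 by 3.15 and Ly6c1 by 3.81 in binucleated cells, and 5 and 4 of 7 leukocyte markers rose and 1 and 0 fell (medians 4.76, or 4.68 with genes at 0 set to their bound, and 2.4, estimated-correlation p = 0.092 and 0.096). Fibroblast markers went both ways, 3 higher and 3 lower in mononucleated and 5 and 3 in binucleated cells.

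Of all genes, 4993 changed from P7 to the adult in mononucleated cells (2303 rose, 2690 fell) and 4461 in binucleated cells (2086 rose, 2375 fell). Camera called 15 lists in each class, and 9 and 4 held with an estimated correlation. These splits rested on the deposited scaling: with libraries scaled to their total counts the medians of all genes were −0.32 and −0.25 (from −0.01 and −0.03) and the splits became 1322 higher and 4078 lower in mononucleated and 1416 higher and 3467 lower in binucleated cells. The smaller list medians above therefore hold relative to the deposited scaling only. With a fold of at least 1 log2 unit, 2844 and 2524 genes passed.

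Across genes, which are not independent replicates, the class differences of the 3 ages correlated weakly with one another. Noise in the fold changes lowers such correlations, so low values do not show that the class differences are unrelated. Pearson's r between the log2 fold changes was −0.12 ± 0.12 (jackknife SE over libraries) for E18.5 and P7, −0.03 ± 0.09 for E18.5 and the adult, and 0.17 ± 0.07 for P7 and the adult, with Spearman's rho of −0.07, −0.05 and 0.2. Genes called lower in both P7 and adult binucleated cells were Top2a, Ndn and Slit2, a guidance cue gene, 3 against 0.206 expected from independent lists. In addition, 5 genes were higher at E18.5 and lower at P7 (Tagln2, Mxra8, Igfbp7, Serpinb1a and Lyz2) against 1.83 expected. Apart from Top2a, Ndn and Lyz2, these were named after their values were seen. The class difference at P7 ran along the change from E18.5 to the adult, measured in other libraries, with r = 0.32 ± 0.06 (rho 0.3), and with r = 0.27 when the 195 cell cycle genes were left out. The E18.5 difference against adult minus P7 gave r = 0.09 ± 0.03 with rho of −0.04, of opposite sign, and the adult difference against P7 minus E18.5 gave r = 0.02 ± 0.11 (rho 0.07).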

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

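The tests of explanations in this part were chosen only after the result was seen, except those of gene length, GC content and other splits of the samples that disregard the pairs, whose comparison by kept grouping was also chosen afterward.

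Each value in this paragraph was taken up because the class difference, binucleated minus mononucleated, differed between 2 ages by the limma interaction test. From E18.5 to P7 it differed in 281 genes. Lists called with both correlations moved by medians of −1.81 (DNA replication and G1/S), −1.82 (G2/M), −0.47 (E2f, Rb and cyclin regulators), −0.46 (centrosome), 0.31 (excitation-contraction), 0.44 (fatty acid oxidation), 0.29 (ventricular identity), −2.3 (conduction), −3.72 (fibroblast), −2.97 (endothelial) and −3.79 log2 units (leukocyte). The genes were Plin5 (1.27), Il13ra1 (1.54), Tnfaip2 (1.17), Fbxo40 (1.18), Col3a1 (−3.83), Mgp (−3.79), Adamtsl2 (−3.07) and Neil3 (−3.2). Neil3 kept its call without any 1 of the 12 libraries. With the block at P7 and in the adult alone, Plin5, Il13ra1, Tnfaip2, Col3a1 and Fbxo40 lost the call (limma adjusted p = 0.0698, 0.125, 0.123, 0.112 and 0.126). All but Neil3 lost it in 3 to 11 of those 12 fits, with a highest limma adjusted p of 0.0563 and 0.118 (Plin5 and Fbxo40, without P7 binucleated replicate 3), 0.105, 0.122 and 0.129 (Il13ra1, Tnfaip2 and Mgp, without P7 mononucleated replicate 3), and 0.11 and 0.0577 (Col3a1 and Adamtsl2, without P7 mononucleated replicate 1). From P7 to the adult it differed in 25 genes, and list medians moved by 1.64 (replication), 0.39 (E2f, Rb and cyclin regulators), 0.26 (centrosome), −0.22 (excitation-contraction), −0.26 (fatty acid oxidation) and −0.26 (ventricular identity). The genes were Cdc45 (2.04), Ccne1 (2.19), Ccne2 (2.21) and Mcm7 (2.24), which without P7 mononucleated replicate 3 had limma adjusted p of 0.184, 0.13, 0.08 and 0.13. With the block at P7 and in the adult alone, Cdc45 and Mcm7 lost the call (0.0896 and 0.071).

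Other splits of the same libraries tested whether chance groupings call as many genes. For the E18.5 to P7 interaction the real grouping gave the most of 100 (281 genes, 105 at most in the others). The 85 others that kept the real grouping at neither age gave 3 genes at most, because a real class difference then counts as spread. Those that kept 1 real grouping carry its class difference, and 0 of 7 at P7 and 0 of 7 at E18.5 gave as many. The real count topped every split tried, but such splits are no clean measure of chance. The 100 were not all possible splits, since a split counted below gave 198 genes without a block. For the P7 to adult interaction 7 of 100 gave as many or more (25 genes, 90 at most in the others), so chance was not excluded. The 6 others all kept the real P7 grouping and so carry the P7 class difference; the 84 that kept the real grouping at neither age gave 1 gene at most. The splits are therefore no clean measure of chance for this interaction, and it stays undecided. These splits disregard the pairs of P7 and adult libraries. Among splits that part every pair, the P7 to adult count was reached in 8 of 32 with the block (12 genes, 191 at most in the others) and in 7 of 32 without it (163 at most), so chance was not excluded there either. Here too, all 7 other splits that kept the real P7 grouping reached the count with the block (6 of 7 without it), so the same reserve holds. For the E18.5 to P7 interaction, with the P7 pairs parted, 1 of 80, the real one, gave the count (281 genes, 198 at most in the others). With replicate numbers as blocks at P7 and in the adult it was again 1 of 80 (204 genes, 148 at most). With blocks at E18.5 too, where the numbers were not treated as pairs, 17 of 80 gave the 291 genes or more (4519 at most). It was 1 of 32 when same-numbered E18.5 libraries were also parted (87 at most). For contrasts of 3 against 3 libraries there are only 10 splits, of which 1, the real one, gave the count or more; 10 are too few for a share under 0.05. The real count and the highest other were 97 and 13 (class at E18.5), 256 and 0 (P7), 11 and 6 (adult), 2231 and 0 (P7 against E18.5, mononucleated), 4332 and 1 (binucleated), 4993 and 0 (adult against P7, mononucleated) and 4461 and 0 (binucleated), all from limma.

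Markers of other cell types were higher in E18.5 binucleated libraries, in 93.3% of fibroblast, 100% of endothelial and 85.7% of leukocyte markers. The outlying binucleated replicate 1 alone is excluded as the cause, since the lowest of the 3 list medians was 3.08 without it. RNA of other cells in the binucleated libraries remains a candidate explanation, although a sort on the yellow protein, which the sources used here do not describe, would remove cells with no history of the Cre. The shares, 85.7% at the lowest, restate the pattern and do not test it. The ventricular identity list, which such RNA would dilute, had a median of −0.08 (camera adjusted p = 0.29), which a small share of other cells would not move. Abundant genes of the lists went from 983 to 8136 (Postn), 723 to 7418 (Col1a2) and 296 to 4129 recovered counts (Dcn). Expression of these genes in the sorted myocytes themselves was not tested apart from RNA of other cells. All 15 fibroblast and 17 endothelial markers also had counts in mononucleated libraries (3 of the 7 leukocyte markers had 0). Such counts decide nothing, because the mononucleated libraries may hold RNA of other cells too. A difference between the classes at that age, which the design names, was not tested apart from these.

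G2/M genes were higher in binucleated cells at E18.5 (median 0.82) and lower at P7 (−1.06). Cells in G2 or mitosis sorted as binucleated, which could happen if the sort went by DNA content (the sources used here do not say), are not excluded at E18.5: the cytokinesis list, which shares no gene with the G2/M list, had a median of 0.33 that camera did not call with an estimated correlation (adjusted p = 0.33). Cycling cells of other types in the E18.5 binucleated libraries are not excluded either. The replication list, with a median of −0.11, gave them no support, but cells sorted in G2 or mitosis would bring few of its transcripts, and markers of other cells were higher in the same libraries. Without binucleated replicate 1 the G2/M and replication medians were 0.9 and −0.02. A change of the cell cycle in myocytes with age is among the open explanations and was not tested apart from them.

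Binucleated replicate 1 at E18.5 stood apart from its group, with 603 genes over 2 log2 units lower and 198 higher than the mean of its 2 fellow libraries. Marker medians of fibroblasts, endothelial cells and leukocytes deviated by −1.2, −0.87 and −0.68, against the direction that more RNA of these cells would give. They do not exclude it, because a length bias, left open below, may have lowered markers with long messages. Erythroid markers deviated by 0.79, and more RNA of those cells was not tested. GC content is excluded, since it held 0.458% of the variance of the deviation. Gene length held 14.6% (Spearman's rho −0.4 across the 99% of genes with a length), with short messages in excess: ribosomal protein genes deviated by 1.54, oxidative phosphorylation by 1.15 and histones by 1.9. That share is neither small nor large enough to decide, so a length bias may be part of the cause and cannot be told apart from a real excess of those short messages. No biological explanation was tested for a single library.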

How the results depend on the processing

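Voom weights, array weights, total-count scaling, a replicate block at P7 and in the adult alone, the added count filter and fits without E18.5 binucleated replicate 1 outside its own contrasts were chosen after the data were seen. Of 6452 alternative values of named genes, 6011 kept their side of the threshold, 379 lost a call, 57 gained one and 5 reversed; of 2332 values of lists the numbers were 2134, 145, 45 and 8. Reversed means that the direction (camera's for lists) changed with a call in at least 1 of the 2 settings. A further 62 gene values and 101 list medians changed sign without that, such as Myl2 for adult against P7 in mononucleated cells (−0.015 without P7 mononucleated replicate 1). Quantile normalization reversed Myl2 (−0.512), Sdha (−0.073) and Tnnt2 (−0.082) and the lists of oxidative phosphorylation (−0.156) and glycolysis (−0.092) for adult against P7 in mononucleated cells. It reversed Sdha (−0.086) and oxidative phosphorylation (−0.202) in binucleated cells, and Tnnt2 (−0.482) and oxidative phosphorylation (0, to 3 decimals) for P7 against E18.5 in binucleated cells, and oxidative phosphorylation in the E18.5 to P7 interaction (−0.139). Leaving out E18.5 binucleated replicate 1 reversed oxidative phosphorylation (−0.137, range over leave-outs to 0.432) and ribosomal proteins (−0.104, to 0.65) at E18.5. It also reversed ribosomal proteins in the E18.5 to P7 interaction (−0.573 to 0.186). Counts of genes past the threshold moved by over 1.5 times as follows, and the cause was not tested. With array weights, which gave that library a weight of 0.05, the counts were 338 (class at E18.5), 1401 (P7), 52 (adult), 5177 (P7 against E18.5, mononucleated), 1199 and 233 (interactions). With voom weights they were 204 (E18.5), 0 (adult), 430 and 1 (interactions). In fits of only the libraries compared they were 0 (E18.5), 608 (P7), 0 (adult), 3875 and 2069 (P7 against E18.5, mononucleated and binucleated). The counts of 0 are from limma, whose fit to all libraries had 1679 (E18.5) and 301 (adult) genes at an unadjusted p under 0.05. The 301 are fewer than a share of 0.05 of the 12048 genes. Quantile normalization gave 5 in the adult, and total-count scaling 42 in the P7 to adult interaction. A log2 fold of at least 1, a stricter criterion by construction, gave 1197 and 2265 (P7 against E18.5, mononucleated and binucleated) and 2844 and 2524 (adult against P7). With the replicate block the count was 25 in the adult and 12 in the P7 to adult interaction, and with it at P7 and in the adult alone 8 in that interaction. That narrower block took Slc16a12, Sord, Cdc6, Gucy1b1, Coq3 and Polr1e below the threshold at P7, and called fetal growth genes there (camera adjusted p from 0.096 to 0.04; 0.33 with an estimated correlation and no block) but not interferon response in the E18.5 to P7 interaction (0.04 to 0.052). At E18.5, where the numbers were not treated as pairs, the block gave 104 genes against 97, 79 of them in both. For the E18.5 to P7 interaction it gave 291 against 281. At E18.5 camera with the block also called erythroid markers (adjusted p from 0.09 to 0.011) and, in the E18.5 to P7 interaction, erythroid markers (0.0069) and sex-linked genes (0.039). With the narrower block, camera called erythroid markers in that interaction (adjusted p = 0.005) and not sex-linked genes (0.067). In the P7 to adult interaction the block at all ages added fetal cardiac isoforms (camera adjusted p from 0.21 to 0.016), and the narrower block did not (0.11). With an estimated correlation and no block these 4 had adjusted p = 0.55, 0.42, 0.65 and 0.51. With numbers shared between ages it ended the oxidative phosphorylation call for adult against P7 in binucleated cells (0.049 to 0.056). Apart from these and the calls given with the comparisons, it took Cdc6, Coq3, Polr1e and Gucy1b1 below and Acot2, Egr2 and Hspa1b past the threshold at P7. It took Il13ra1, Tnfaip2, Col3a1, Fbxo40 and Cdc45 below it in the interactions, and changed no other list call. Leaving out 1 library gave 79 to 282 genes for class at E18.5 (lowest without mononucleated replicate 1, highest without binucleated replicate 3), 129 to 574 at P7 (without P7 mononucleated replicate 3 and E18.5 binucleated replicate 1), 2 to 23 in the adult (without mononucleated replicate 2 and E18.5 binucleated replicate 1). It gave 1628 to 3901 for P7 against E18.5 in mononucleated cells (without E18.5 mononucleated replicate 2 and E18.5 binucleated replicate 1), 160 to 568 for the E18.5 to P7 interaction (without P7 mononucleated replicate 3 and E18.5 binucleated replicate 1) and 0 to 102 for the P7 to adult interaction. In that interaction the count was 0 without P7 binucleated replicate 2 or P7 mononucleated replicate 3, 4 without P7 binucleated replicate 1 or P7 mononucleated replicate 2, 9 without P7 binucleated replicate 3 or adult mononucleated replicate 1, 12 without adult binucleated replicate 2, 7 without adult mononucleated or binucleated replicate 3, and 102 without E18.5 binucleated replicate 1. The other age counts ran from 4196 to 6484 and 3693 to 6061 (adult against P7, mononucleated and binucleated) and 3314 to 5036 (P7 against E18.5, binucleated). Correlations of class effects ran from −0.194 to −0.071 (E18.5 and P7), −0.09 to 0.025 (E18.5 and adult), 0.115 to 0.178 (P7 and adult) and 0.279 to 0.334 (P7 against adult minus E18.5). Robust moderation moved no count by over 1.5 times. Both filters removed 0 genes and test nothing, the pseudocount alternative did not apply, and lists were not rerun with array or voom weights, total-count scaling, robust moderation or only the libraries compared. Depth limits the adult cell cycle genes, several of which had 3 or fewer counts over a class.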

Other observations

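The test of atrial genes in this part was chosen only after the result was seen, and its criterion was tightened after its values were known.

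Besides the markers described above, immediate early and dissociation stress genes were higher in the adult than at P7 in both classes. Of 27 measured genes 21 rose in mononucleated cells (median 1.57) and 21 rose and 1 fell in binucleated cells (median 1.52). Zfp36, a messenger RNA decay factor gene, rose by 3.33 and Ier2 by 2.69 in binucleated cells (limma). Camera's preset correlation called both (adjusted p = 7.7e-07 and 7.5e-07), and the estimated correlation neither (adjusted p = 0.33 and 0.36). Yap targets had medians of 0.7 and 0.79 over that interval, with 6 of 13 higher and 2 lower in each class, and were not called by camera (adjusted p = 0.19 and 0.12). Ccn1, a matricellular protein gene, rose by 3.03 in binucleated cells.

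Erythroid and sex-linked genes varied between libraries of 1 group. The mean of 6 erythroid genes, relative to all libraries, was −4.15, −0.13 and −0.75 in adult mononucleated replicates 1, 2 and 3 and −4.3, −2.42 and −1.15 in binucleated replicates 1, 2 and 3. The mean of 4 sex-linked genes was 1.25 and 1.33 in adult replicate 1 of the 2 classes, from −0.3 to 0.33 in the other adult libraries, and −1.69 in E18.5 binucleated replicate 1 against 0.32 and 0.05 in its fellow libraries.

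A hypothesis for the lower conduction and atrial transcripts of P7 binucleated cells is that the mononucleated libraries held more atrial myocytes. Lower atrial transcripts are part of the pattern itself, so low values of atrial genes restate it and lend the hypothesis no support. Atrial myocytes would bring Sln, Myl4 (also on the list of fetal cardiac isoforms) and Myl7. The mean log2 fold change of these 3 genes was −1.55, in the direction the hypothesis needs. Its SE of 0.55 was taken over the 3 genes, which are not replicates, and not over libraries. Their single values of −2.49 ± 1.4, −0.57 ± 0.36 and −1.58 ± 0.99 did not pass the limma test (adjusted p = 0.644, 0.725 and 0.726), and Sln rested on 32 against 3 counts, a ratio of 9.28 (95% exact counting interval 2.9 to 47.4). A sort on the yellow protein, which the sources used here do not describe, would remove atrial myocytes with no history of the Cre, and no table here tests that. The values decide neither for nor against it, and a lower level of these genes in ventricular myocytes with 2 nuclei may give the same picture.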
